A study of Mus musculus with 6 samples.

How the data were processed

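Liver RNA of 6 male mice aged 9 weeks was measured on single-colour Affymetrix Mouse Genome 430 2.0 arrays, with 1 mouse per array. Per the labels, 3 mice were conditional Keap1 knockouts, in which Cre recombinase under the albumin promoter acted on a floxed Keap1 allele opposite a null allele. The other 3 were genetic controls with the same Cre, a floxed allele and a wild-type allele. All 6 had received only the vehicle, made of 10% DMSO, 10% Cremophor-EL and 80% PBS. Groups and replicate numbers were taken from the labels, which number the knockouts 3, 4 and 5 and the controls 1, 2 and 3. No scan date or batch was used here.

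The deposited values are linear array intensity, 1 number per probe set and array. Per the labels' protocols, total RNA was reverse transcribed from a T7-oligo(dT) primer, transcribed into biotin-labelled cRNA, fragmented and hybridised with added control transcripts. The software that summarised the probes and its version are not given in the sources used here, nor were detection calls used. The mean of each array without the lowest and highest 2% of probe sets was 500.0, so the authors' values had been scaled to a shared target. Such scaling sets the average signal of every array equal, and a change in the total amount of RNA per cell would not be seen. The arrays held 45101 probe sets, of which 64 were control probe sets. In the platform's probe table, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. No symbol needed updating through its Entrez number. Genes were named only from probe sets with 1 symbol, which covered 18193 genes. The genome build is not given in the sources used here, and no coordinates are printed. Which genes neighbour Keap1 was read from the RefSeq genes of assembly GRCm38.p6.

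From these values log2(signal + 16) was computed, and fold differences are on that scale, which understates the change of dim genes. Between 11.9% and 16.5% of the values on an array were under 16. Probe sets entered the tests if their mean over the 6 arrays was at or above the 40th percentile, which left 27022 probe sets. Each gene was represented by its probe set with the highest mean, which gave 13027 genes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The labels' replicate numbers do not pair the mice, since the groups share only the number 3. The number of arrays limits the precision, and an exact permutation test of a single value cannot go below p = 0.1 with 3 mice against 3.

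Before the data were examined, 29 gene lists were fixed from textbook knowledge, with 630 entries, of which 66 had no probe set of their own. The lists cover the NRF2 pathway, drug metabolism, lipid and glucose metabolism, stress responses, sex-biased genes, zonation and markers of hepatocytes and of other cell types. They were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes, and fry asks whether the genes of a list move one way. For each list the genes past the threshold were counted with adjustment over all genes and over the list alone. In the text a gene "rose" or "fell" if it passed the threshold over all genes.

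Named genes were chosen by a rule fixed before the data were examined. It takes the 12 higher and 12 lower genes with the largest difference among those past the threshold whose groups do not overlap, Keap1 and Nfe2l2, and up to 4 members of each list that passed, or the 2 with the largest difference where none did. Of the 84 genes named by this rule, 60 passed the threshold. Among those, 25 had a further probe set, and for 1, Rab3a, it differed in sign. The steps were tested on simulated arrays of 13027 genes made from the means and spread of these arrays, with the spread of each gene drawn toward that of genes of like signal, which favours a fit with the variance trend. At 1.5-fold 92% of the changed genes were recovered, at 2-fold 94%, and at 4-fold and 8-fold 100%. These shares describe the simulated spread and may overstate the recovery in the real arrays. There Marco, Cdkn1a and Usp2 differed by 2.65-fold, 2.50-fold and 2.19-fold without passing (limma adjusted p = 0.111, 0.0947 and 0.0705). Of 196 calls 3 were false, and 0 of 29 unchanged lists were called. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called without a change.

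The alternatives fixed beforehand were no filter and a filter at the 60th percentile, offsets of 1 and 64, quantile normalization, median centring and cyclic loess, eBayes without the trend or robust, array weights, the mean over a gene's probe sets, leaving out probe sets that can match several transcripts, a Welch test per gene, and leaving out each array. Scaling on the 9 hybridisation control probe sets was added after seeing the data.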

Results

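Gene expression was measured in the livers of 3 conditional Keap1 knockout mice and 3 genetic controls, all male, aged 9 weeks and given vehicle only. KEAP1 is the adaptor through which a CUL3 ubiquitin ligase marks the transcription factor NRF2, encoded by Nfe2l2, for degradation. The design asks which hepatic genes differ when the floxed allele lies opposite a null allele rather than a wild-type one. The controls had the same Cre, so where it acts they keep only the wild-type allele. The null allele of the knockouts does not depend on Cre, so it is not limited to the cells where Cre acts. Correlations of log2 signal across the probe sets tested, which are not independent replicates, were 0.967 to 0.973 between arrays of a group and 0.956 to 0.962 between groups. The first principal component held 34.8% of the variance and separated the groups. The ratio of 3′ to 5′ actin probe sets, a sign of RNA quality, lay between 1.54 and 1.90 with both ends among the controls.

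Keap1 itself was lower in the knockouts. Its brighter probe set had a signal of 230 ± 88.6 in the knockouts and 776 ± 72.1 in the controls (SD, n = 3 each), or 29.7% of control, a log2 difference of -1.74 with a standard error of 0.24 (limma adjusted p = 0.0118). A second probe set stood at 62.5% of control, with a log2 difference of -0.71 and an adjusted p of 0.223 over all probe sets. Whether either probe set lies in the deleted part of the gene is not given in the sources used here, so the level is a limited check of the labels. Nfe2l2 fell, from 3958 ± 307 to 2506 ± 351 (log2 difference -0.66, adjusted p = 0.0303), while its dimmer probe set differed by -0.18 (adjusted p = 0.719). The Nfe2l2 call held without knockout 4 but was lost without each other array (adjusted p = 0.115 without knockout 3, 0.0956 without knockout 5, and 0.0636, 0.0993 and 0.0764 without controls 1, 2 and 3), after median centring (0.148), without the variance trend (0.113) and in the mean over its probe sets (0.156). Without the variance trend the adjusted p of the brighter Keap1 probe set was 0.0561 over all probe sets, without a call, and 0.0494 over genes, with one. Without any 1 control the gene was represented by the second probe set, at -0.78, -0.66 and -0.69 without controls 1, 2 and 3, and was not called.

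The largest rises were those of Cbr3, Apela and Osbpl3. Over the other settings the smallest log2 differences were 3.91 for Apela, 3.76 for Osbpl3 and 4.16 for Abcc4, so the order behind Cbr3 depends on the processing. Cbr3, a carbonyl reductase, had a signal of 20127 ± 5173 in the knockouts and 213 ± 189 in the controls (SD, n = 3 each), 106-fold higher (log2 difference 6.73, standard error 0.46, adjusted p = 0.000219), or 164-fold without control 2. Apela, which encodes a ligand of the apelin receptor, was 44.9-fold higher, although its control mean of 6.93 lay under the offset and its fold therefore depends on it. The efflux transporter Abcc4 rose 20.6-fold, with the lowest adjusted p of all genes (1.59e-06). Gpx2, a glutathione peroxidase, rose from 53.6 ± 20.4 to 1082 ± 234. The metallothionein Mt2 rose 13.7-fold, and Mt1 rose from 856 ± 236 to 10449.9 ± 3014. Slc22a12, a urate transporter, rose 13.6-fold. Tinag, Anxa13, Nrxn2 and Serpinb1a rose by 3.10, 3.03, 2.71 and 2.66 on the log2 scale. The steepest falls were those of Hsd3b5 and Nxpe2. Hsd3b5, a male-biased steroid reductase, fell from 7517 ± 2359 to 530 ± 434 (17.8-fold lower, adjusted p = 0.0146). It was 10.2-fold lower without knockout 4 and 27.8-fold lower without knockout 5. Its call was lost without control 1 (adjusted p = 0.0508), without the variance trend (0.0647) and with robust eBayes (0.0882). Nxpe2 was 11.8-fold lower. The control signals of Tinag (9.2, 80.1 and 7.2) and the knockout signals of Nxpe2 (10.8, 104 and 23.1) lay near or under the offset in several mice, so these sizes depend on it too, from 2.05 to 3.22 for Tinag and from -4.22 to -2.64 for Nxpe2 on the log2 scale over the other settings. On that scale Tinag differed by 3.76 without control 2 and Nxpe2 by -4.20 without knockout 4. Cd33 and Lat, which encode a lectin and an adaptor of leukocytes, were 4.80-fold and 4.07-fold lower, sizes that also depend on the offset (log2 differences of -2.73 to -1.54 and -2.21 to -1.35 over the other settings). Elovl3, a fatty acid elongase, was 3.72-fold lower and Rtp4 3.24-fold lower. Rab3a fell by 1.87 on the log2 scale in its brightest probe set, while another of its probe sets differed by 0.49 in the other direction.

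In all, 258 of 13027 genes changed, 135 higher and 123 lower in the knockouts (limma, Benjamini-Hochberg). Of these, 229 changed at least 1.5-fold, 114 higher and 115 lower, and 129 at least 2-fold, 70 higher and 59 lower. The groups did not overlap in 2770 genes, or 21.3%, where chance gives 10%, and these included all 258 changed genes. Over probe sets, 410 of 27022 changed, 217 higher and 193 lower, of which 41 had no or several gene symbols. The share of higher calls was 52.3%, but 64.9% after median centring (137 higher, 74 lower) and 20.2% after scaling on the hybridisation controls (84 higher, 332 lower), which moved the median of all genes by -0.19. The count was 77 without the variance trend, 0 with a test that both takes the variance of each gene alone and lets it differ between groups (1334 at an unadjusted p under 0.05), and 94 without knockout 3, 133 without knockout 5, 121 without control 1, 133 without control 2 and 169 without control 3. Of the 60 named genes that passed, 25 did so in every run without 1 array and 6 in none, Acox2, Cyp2c39, Cyp2g1, Insig1, Mafg and Psmb5, while 11 passed in 1 such run, Nfe2l2, Acly, Dnajb9, Fads1, Gsr, Susd4, Tinag, Ugp2, Neto1, Slc6a9 and C730036E19Rik. The calls nearest the threshold among named genes of the lists were those of Fads1, Insig1, Dnajb9, Acox2, Cyp2c39, Psmb5 and Cyp2g1 (adjusted p = 0.0485, 0.0479, 0.0461, 0.0443, 0.0429, 0.0416 and 0.0416).

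**Figure D1:**
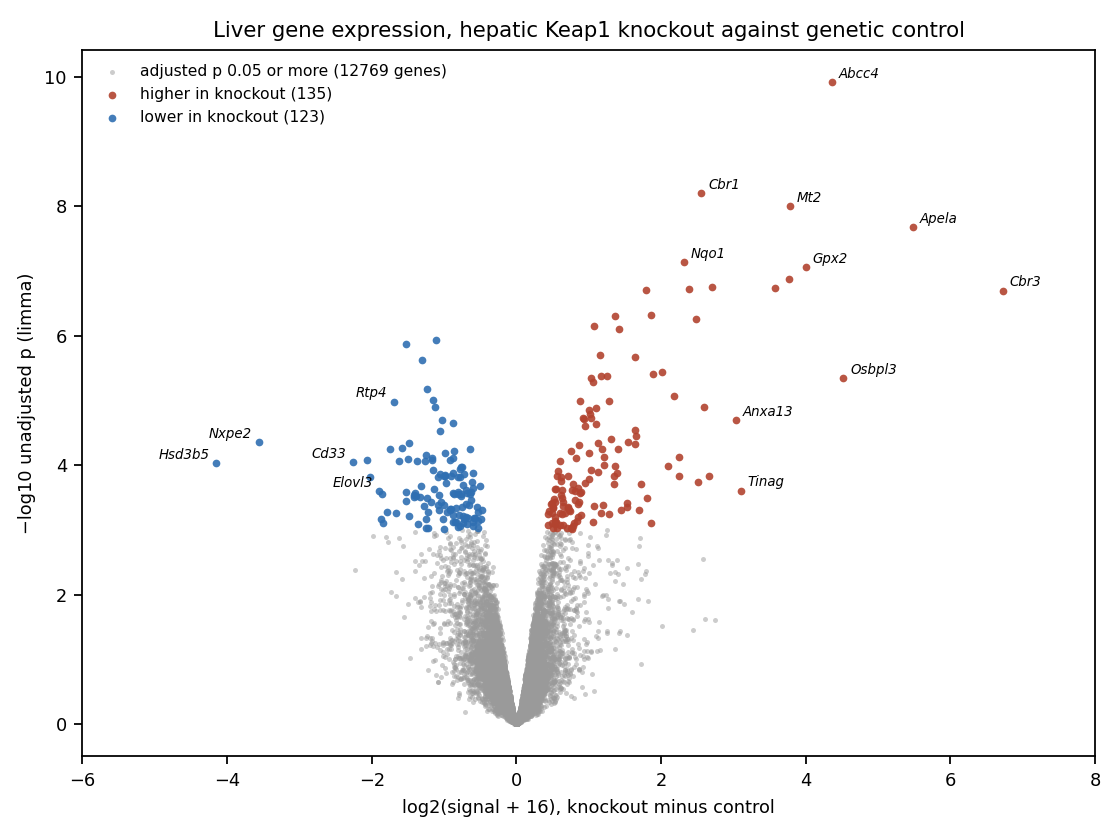
Log2 difference of log2(signal + 16), knockout minus control, against the negative log10 of the unadjusted limma p, with 1 point per gene (3 mice per group). Red points are the 135 genes that were higher and blue points the 123 that were lower at an adjusted p under 0.05; Cbr3 lies farthest right at 6.73 and Hsd3b5 farthest left at -4.15.

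Genes of the antioxidant and glutathione systems were higher together. Among the antioxidant and NADPH-dependent reductases, 7 of 25 measured members rose and 0 fell (16 rose and 2 fell adjusted over the list alone; camera adjusted p = 1.15e-12, adjusted p = 0.203 with an estimated correlation). After Cbr3, the largest rises were those of Cbr1, also a carbonyl reductase, at 5.88-fold, the quinone reductase Nqo1 at 4.96-fold, from 549 ± 101 to 2766 ± 228, and the sulfiredoxin Srxn1 at 3.65-fold. In glutathione synthesis and recycling, 6 of 16 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 8.31e-10, adjusted p = 0.135 with an estimated correlation). They included Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, at 2.26-fold, and the glutathione reductase Gsr at 1.64-fold. Of the glutathione S-transferases, 5 of 19 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 5.83e-10, adjusted p = 0.307 with an estimated correlation). Gsta2 rose 5.23-fold, Gstm3 4.77-fold, Gstm2 3.46-fold and Gstm4 3.14-fold, and a probe set shared by Gsta1, Gsta2 and Gm3776 was higher by 2.71 on the log2 scale. These 3 lists kept their call under every normalization and without any 1 array.

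Among NRF2 pathway components, 1 of 13 rose and 2 fell (2 and 2 adjusted over the list alone). The small Maf protein Mafg, a binding partner of NRF2, rose 1.42-fold, and Keap1 and Nfe2l2 fell. The list was not called (adjusted p = 0.974), with a median of 0.01, a mean of -0.17 and a test direction of higher. In NADPH generation and the pentose phosphate pathway, 1 of 13 rose, Pgd at 2.19-fold, and 3 did adjusted over the list alone (adjusted p = 0.0347, adjusted p = 0.529 with an estimated correlation).

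**Figure D2:**
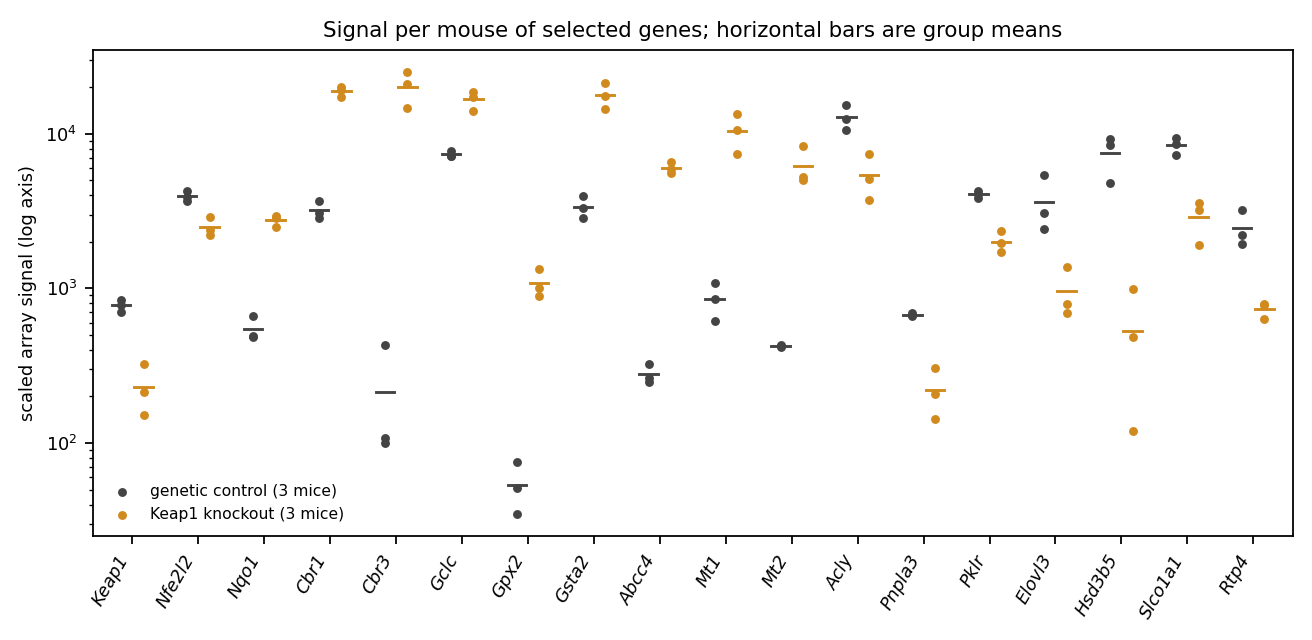
Scaled array signal on a log axis for 18 genes, with 1 point per mouse, 3 genetic controls in grey and 3 Keap1 knockouts in orange, and bars at the group means. The points of the groups do not overlap for these genes; Nqo1 stands at 2766 in the knockouts against 549 in the controls, and Hsd3b5 at 530 against 7517.

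In glucuronidation and sulfation, 3 of 20 rose and 0 fell, Ugdh, which makes UDP-glucuronic acid, at 2.01-fold, Ugp2 at 1.67-fold and Ugt2b35 at 1.53-fold (6 rose and 4 fell adjusted over the list alone; adjusted p = 0.00395, adjusted p = 0.520 with an estimated correlation). Of the hepatic transporters, 3 of 23 rose and 2 fell (4 and 3 adjusted over the list alone), without a call for the list (adjusted p = 0.228; median -0.05, mean 0.18, test direction higher). Besides Abcc4, the canalicular exporter Abcc2 rose 1.71-fold, while the uptake carriers Slco1a1 and Slc22a7 fell, 2.98-fold and 2.81-fold. Of the xenobiotic cytochromes P450, 22 of 30 lay above the controls and 2 rose, Cyp2g1 at 1.79-fold and Cyp2c39 at 1.74-fold (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.00617, adjusted p = 0.551 with an estimated correlation). Outside that count, a probe set shared by Cyp2a4 and Cyp2a5 was higher by 0.97 on the log2 scale (limma adjusted p = 0.00435 over all probe sets). Its signal went from 17430 ± 2244 to 33957 ± 1930. That of Cyp3a41a and Cyp3a41b, also outside it, differed by -1.53 without passing (adjusted p = 0.227). In bile acid synthesis 2 of 17 rose, the oxysterol hydroxylase Cyp39a1 at 2.54-fold and the peroxisomal oxidase Acox2 at 1.52-fold (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.0347, adjusted p = 0.520 with an estimated correlation). The calls of the glucuronidation, P450, bile acid and NADPH lists were lost after both quantile and cyclic loess normalization (adjusted p = 0.0897, 0.637, 0.987 and 0.282 after quantile). The glucuronidation, bile acid and NADPH calls were lost after median centring too (0.0774, 0.0774 and 0.0697), and the bile acid and NADPH calls after scaling on the hybridisation controls (0.0562 and 0.0664). Without knockout 4 they were lost as well (adjusted p = 0.0608, 0.236, 0.0780 and 0.311), the P450, bile acid and NADPH calls also without control 3 (0.155, 0.325 and 0.150), and the bile acid and NADPH calls also without knockout 3 (0.0639 and 0.0521).

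Genes of lipid synthesis were lower. In fatty acid and triglyceride synthesis, 0 of 21 rose and 5 fell, and 17 had values below the controls (1 rose and 10 fell adjusted over the list alone; adjusted p = 5.77e-06, adjusted p = 0.520 with an estimated correlation and 0.165 with fry). Pnpla3, a lipid-droplet protein induced by feeding, was 3.07-fold lower, at 219 ± 82.9 against 675 ± 18.2 (SD, n = 3 each). The ATP citrate lyase Acly was 2.42-fold lower, the desaturase Fads1 2.01-fold and the elongase Elovl5 1.78-fold. In cholesterol synthesis and uptake, 2 of 20 fell and 19 lay below the controls (4 fell adjusted over the list alone; adjusted p = 5.20e-06, adjusted p = 0.529 with an estimated correlation and 0.251 with fry). These were Insig1, a regulator of sterol sensing, at 2.32-fold lower, and the sterol carrier Stard4, at 2.11-fold lower. In fatty acid oxidation and ketogenesis 0 of 25 passed the threshold over all genes or adjusted over the list alone, and 22 lay below the controls (adjusted p = 0.0228, adjusted p = 0.638 with an estimated correlation). Its largest differences were those of Bdh1 at -1.04 (adjusted p = 0.122) and Fgf21 at 1.03 (adjusted p = 0.388), which was 0.48 without knockout 3. Glucose metabolism was not called (1 of 16 rose, 1 fell; 1 and 2 adjusted over the list alone; adjusted p = 0.220), but it was called lower after quantile and cyclic loess normalization (adjusted p = 0.0265 and 0.0351, medians -0.32 and -0.33). Pklr, the liver pyruvate kinase, fell 2.03-fold, and Ppp1r3c, which targets a phosphatase to glycogen, rose 2.47-fold. The fatty acid oxidation call was lost without knockout 3, knockout 5 or control 2 (adjusted p = 0.0678, 0.243 and 0.389), after median centring (0.0798) and after scaling on the hybridisation controls (0.0562).

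Male-biased liver genes were lower as a group. Of 13 measured, 4 fell and 0 rose (8 fell and 3 rose adjusted over the list alone; adjusted p = 0.00154, adjusted p = 0.529 with an estimated correlation and 0.165 with fry). Beyond Hsd3b5, Elovl3 and Slco1a1, Susd4 fell 1.83-fold. Of the female-biased genes 0 of 8 passed over all genes or adjusted over the list alone, and 7 lay above the controls (adjusted p = 0.0479, adjusted p = 0.520 with an estimated correlation). Cyp2a4 and Cyp3a41a, also on this list, had only shared probe sets, which differed by 0.97 and -1.53 (limma adjusted p = 0.00435 and 0.227). Cyp2b9 differed by 2.75 (adjusted p = 0.239), at 3192 ± 4829 in the knockouts with 8767 in knockout 4 alone, without which it differed by 1.28 (3.61 without knockout 3 and 3.36 without knockout 5), and Cyp2b10 by 1.49 (adjusted p = 0.188), or 0.80 without control 2. The female-biased call was lost after quantile normalization (adjusted p = 0.0897), cyclic loess (0.0774) and median centring (0.0798), and without knockout 4, knockout 5 or control 3 (0.0897, 0.0557 and 0.104).

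**Figure D3:**
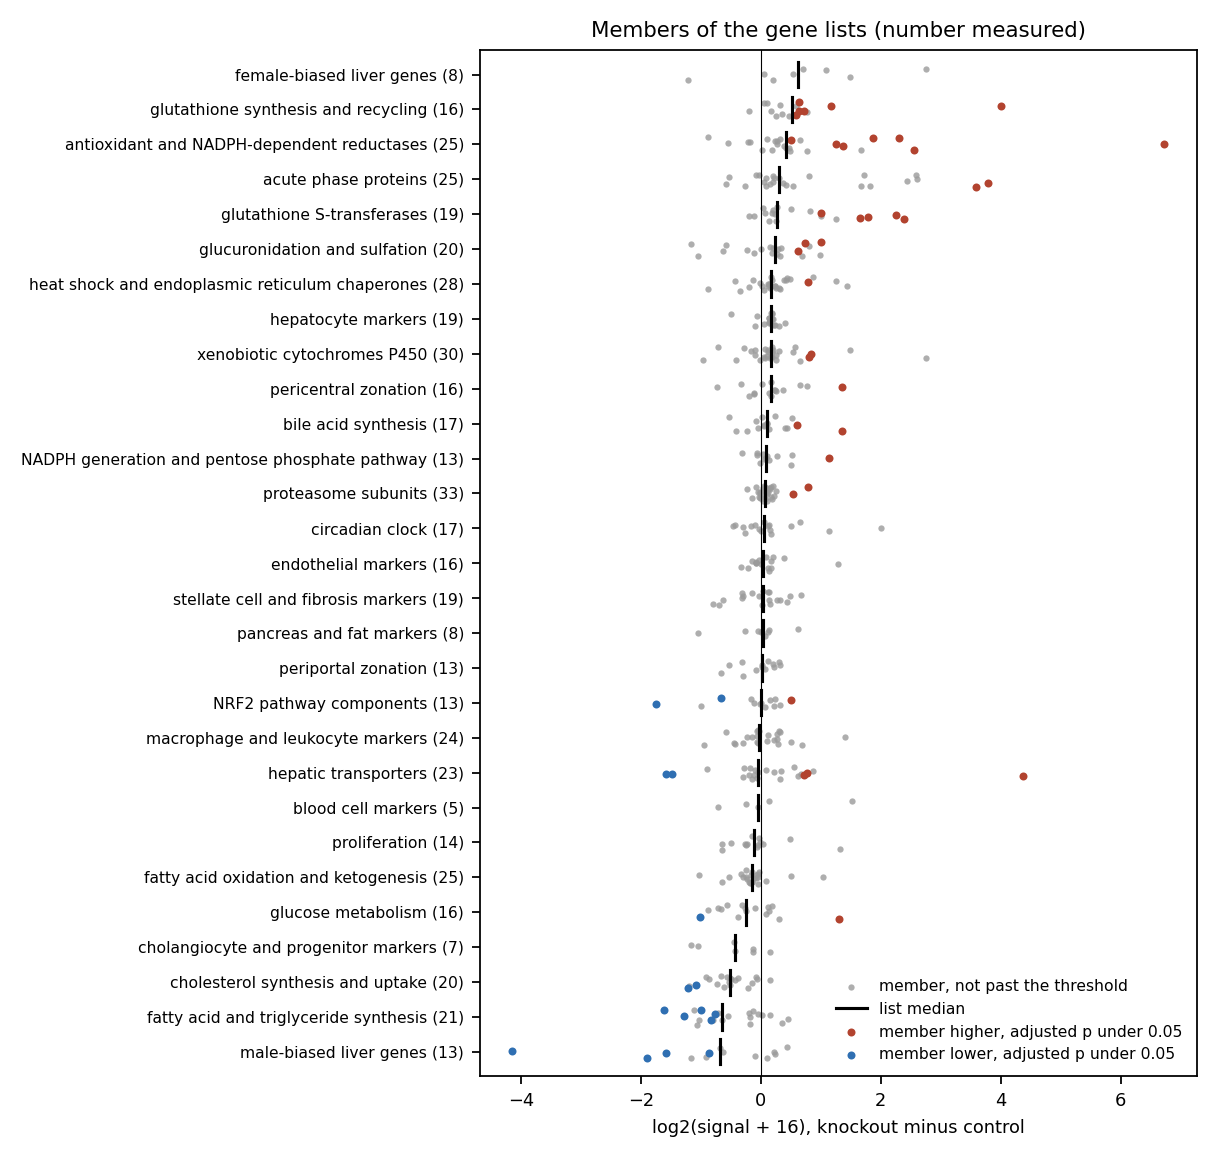
Log2 difference, knockout minus control, of every measured member of the 29 gene lists, with the number measured in brackets and a black line at each list's median. Coloured points passed an adjusted p of 0.05 over all genes, red if higher and blue if lower; the median is 0.53 for glutathione synthesis and recycling and -0.65 for fatty acid and triglyceride synthesis.

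Of the acute phase proteins 20 of 25 lay above the controls and 2 rose, Mt1 and Mt2, which bind metals (5 rose and 2 fell adjusted over the list alone; adjusted p = 3.65e-05, adjusted p = 0.529 with an estimated correlation). Of the proteasome subunits 23 of 33 lay above the controls and 2 rose, Psmd5 at 1.72-fold and Psmb5 at 1.45-fold (2 adjusted over the list alone; adjusted p = 0.0136, adjusted p = 0.529 with an estimated correlation). Of the heat shock and endoplasmic reticulum chaperones 22 of 28 lay above the controls and 1 rose, Dnajb9 at 1.72-fold (1 adjusted over the list alone; adjusted p = 0.00242, adjusted p = 0.529 with an estimated correlation). After quantile normalization the acute phase, proteasome and chaperone lists were not called (adjusted p = 0.143, 0.637 and 0.471), and after cyclic loess only the acute phase list was (0.0476, with 0.697 for the proteasome and 0.321 for chaperones). The proteasome call was also lost after scaling on the hybridisation controls (adjusted p = 0.578) and without knockout 3 or control 3 (0.147 and 0.0639). Proliferation genes and the circadian clock had 0 members past the threshold (1 rose and 1 fell, and 1 rose, adjusted over the list alone) and no call (adjusted p = 0.397 and 0.518). Their largest differences were those of Cdkn1a at 1.32 (adjusted p = 0.0947) and Ciart at 2.01 (adjusted p = 0.264), which was 0.89 without control 3 and 2.70 without control 2.

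Markers of cell types and zones gave few calls. Of the hepatocyte markers 0 of 19 passed over all genes or adjusted over the list alone, and 16 lay above the controls, with a median of 0.17 (adjusted p = 0.00146, adjusted p = 0.600 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.771), cyclic loess (0.591), median centring (0.0613) and scaling on the hybridisation controls (0.0968), and without control 3 (0.0743). In the pericentral list 1 of 16 rose, the ammonium transporter Rhbg at 2.56-fold (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.0564, and a call at 0.0474 after scaling on the hybridisation controls). The periportal list was not called (0 of 13; adjusted p = 0.518, median 0.02, mean -0.05, test direction higher). For macrophages and leukocytes 0 of 24 passed (adjusted p = 0.604; median -0.04, mean 0.05, test direction higher), with Marco at 2.65-fold the control (adjusted p = 0.111) and H2-Aa at a log2 difference of -0.95 (adjusted p = 0.245), or -0.60 without control 1. For stellate cells and fibrosis 0 of 19 passed (adjusted p = 0.604; median 0.04, mean -0.03, test direction higher), for endothelium 0 of 16 (adjusted p = 0.518) and for cholangiocytes and progenitors 0 of 7 (adjusted p = 0.261). For blood cells 0 of 5 passed (adjusted p = 0.966; median -0.05, mean 0.13, test direction higher), and for pancreas and fat 0 of 8 (adjusted p = 0.966; median 0.04, mean -0.05, test direction lower). In the latter, Car3 differed by -1.05 and Retn by 0.62 (limma adjusted p = 0.148 and 0.512). Further probe sets of Car3 differed by -1.78, -2.59 and -2.97, of which only the last passed (adjusted p = 0.0423 over all probe sets). None of these 7 lists, from periportal to pancreas and fat, had a member past the threshold adjusted over the list alone.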

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

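The tests on fasting, on the share of hepatocytes and on Eif2s3y, and the neighbour windows of 50, 200 and 400 genes, were chosen after the results they bear on, or related ones, had been seen. The 9 hybridisation control probe sets, added transcripts outside the comparisons, were higher in the knockouts by 0.1889 on the log2 scale, at 11.39 ± 0.08 against 11.21 ± 0.09 (SD, n = 3 each), in 9 of 9 probe sets, with an exact permutation p of 0.1, the smallest that 3 against 3 allows. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many as 258 genes, and the highest of the others gave 1. The other splits mix knockouts with controls, so the group difference adds to their spread, and their counts are not a level of false calls. With 10 splits no share under 0.05 can be reached.

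Genes of fatty acid and cholesterol synthesis were lower in the knockouts, with a median of -0.56 over the 41 genes of both lists, which ranged from -0.71 to -0.29 without any 1 array and was weakest without control 1. A lower share of hepatocytes would lower hepatocyte markers by a like amount, but their median was 0.1673, and after quantile normalization -0.00112. The bound was -0.278, set at 0.5 times the lipid median, or -0.146 without control 1, where the hepatocyte median was 0.209. The bootstrap 95% interval of 0.130 to 0.189 resampled the marker genes, so it does not measure the spread between mice. Without any 1 array the hepatocyte median ranged from 0.115 to 0.213. After scaling on the hybridisation controls it was -0.0216. Longer fasting of the knockouts may also lower these genes. Fasting-induced genes had a median of -0.1510 (16 measured; limma camera, adjusted p = 0.450 over the 4 lists chosen after the data), which leaves that open. The knockout itself also stays open as an explanation.

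Male-biased genes were lower in the knockouts. Female animals among the knockouts are argued against by Eif2s3y, on the Y chromosome, whose lowest knockout signal was 0.8855 of the control mean, and a single array by the list's camera p, which reached at most 0.002846 without any 1 array. A weaker growth hormone signal may lower male-biased genes. Genes that growth hormone raises in both sexes had a median of -0.2735 (8 measured, 1 fell; limma camera, adjusted p = 0.248 over the same 4 lists), which does not decide it. Of the 8, 5 lay below the controls and 3 above. The 1 that fell, looked up after the test, was Ghr, which encodes the growth hormone receptor. Its signal went from 15707 ± 1934 to 10393 ± 743 (limma adjusted p = 0.0392).

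DNA of another strain beside a targeted Keap1 allele could change genes near it on chromosome 9. Both groups carried a floxed allele, so DNA beside that allele could be in both. Only DNA beside the null allele would be in the knockouts alone. Among the 63 tested genes within 100 annotated genes on each side, 2 were called, Col5a3 and Dpy19l1, which were looked up after the test. The odds ratio against all other genes was 1.634 (95% interval 0.192 to 6.22, Fisher's exact p = 0.354). With 50, 200 and 400 genes on each side it was 1.06, 0.894 and 0.664. The interval is too wide to decide.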

How the results depend on the processing

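Scaling on the hybridisation controls and the interferon list were added after seeing the data. The count of changed genes rests on the variance trend and on each mouse. It was 258, but 77 without the trend, 0 with a Welch test (1334 genes at an unadjusted p under 0.05, lowest adjusted p 0.127), 416 after scaling on hybridisation controls, and 94 to 173 without any 1 array. With knockout 3 left out 94 genes passed, and 88 of these were among the 258. Fewer arrays leave less power. The count at 1.5-fold was 77 without the trend, 404 with hybridisation controls and 94 to 173 without 1 array. Probe sets numbered 271 without a filter, where more are tested, 105 without the trend, 631 with hybridisation controls and 158 to 297 without 1 array. In every setting tried with limma 45 genes passed, and 63 of the 258 passed without any 1 array. Over all probe sets, the Keap1 probe set stayed at -1.74 without the trend but lost its call (adjusted p = 0.0561), while over genes Keap1 kept it (adjusted p = 0.0494). When any control was left out, the gene's brightest probe set became the other one, with differences from -0.78 to -0.66 and no call, while the main probe set kept its call. Other causes were not tested. No paired analysis was possible because the groups share only the replicate number 3.

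The number of called lists was 16, but 8 after quantile normalization, 10 after median centring, 9 after cyclic loess, 0 with an estimated correlation and 3 with fry. The 8 and the 9 include glucose metabolism, not called in the main fit. The 3 were antioxidant reductases, glutathione synthesis and glutathione S-transferases (fry adjusted p = 0.00734, 0.00616 and 0.0333). None of the 4 lists called lower in the main fit was called with fry. Its adjusted p was 0.165 for fatty acid synthesis and male-biased genes, 0.251 for cholesterol synthesis and 0.376 for fatty acid oxidation. Of the 16, 7 kept their call after quantile, 8 after loess, 7 under both, and 8 without any 1 array. Over 1572 comparisons of named genes 243 lost the threshold, 36 of them without the trend, 8 gained it and 1 changed sign, Rab3a at 0.49 without probe sets that can match several transcripts. Over 609 comparisons of lists 80 lost the threshold and 8 gained it. The direction of the test turned in 34, never between 2 calls, and the median changed sign in 52. Those given below are the turned tests and the sign changes of lists called in either fit. A further 32 sign changes, of uncalled lists whose test kept its direction, are not listed. The counting rule for lists was revised after results had been seen, and the rule used is the one first written with the sign changes of called lists added.

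The values below are list medians. After scaling on hybridisation controls they were -0.183 for NRF2 components, -0.111 for NADPH generation, -0.0249 for P450, -0.0925 for bile acids, -0.121 for the proteasome, -0.0180 for chaperones, -0.0216 for hepatocytes, -0.0266 for pericentral genes and -0.153 for pancreas and fat, set against a shift of -0.19 in all genes. After quantile normalization they were 0.0504 for NRF2 components, -0.00622 for bile acids, -0.00112 for hepatocytes, -0.105 for periportal genes and 0.0637 for pancreas and fat. After cyclic loess they were 0.0379 for NRF2 components, -0.0893 for periportal genes and 0.0711 for pancreas and fat. NRF2 components stood at -0.0171 without a filter, 0.101 after median centring, 0.00632 without the trend or with fry and 0.0365 as the mean over probe sets. Pancreas and fat stood at 0.00278 without a filter and 0.0362 as the mean over probe sets. Blood cells stood at -0.0520 with the higher filter or fry and -0.118 with array weights, and proliferation at -0.0344 without probe sets that can match several transcripts. Without 1 array the medians ranged from -0.0393 to 0.128 for NRF2 components, -0.0103 to 0.161 for NADPH generation, -0.0210 to 0.0772 for transporters, -0.162 to -0.0467 for proliferation, -0.0987 to 0.0921 for periportal genes, -0.0220 to 0.148 for macrophages, -0.00833 to 0.109 for stellate cells, -0.459 to 0.110 for blood cells and -0.133 to 0.144 for pancreas and fat. Without control 1 the transporter and macrophage lists were called higher (adjusted p = 0.0337 and 0.0338). The causes were not tested.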

Other observations

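The lists of interferon-stimulated and glucocorticoid-induced genes were chosen after the leading changed genes had been seen, and the test of the glucocorticoid list after related lists had been seen. Genes named here outside the rule were chosen after their values were seen.

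Interferon-stimulated genes were lower in the knockouts. Rtp4, an interferon-induced gene, was 3.24-fold lower, and Ifit1, which binds viral RNA, fell from 1274 ± 229 to 448 ± 110 (SD, n = 3 each; limma adjusted p = 0.0106). A hypothesis from these was that interferon-stimulated genes are lower as a group. Of 31 others measured, 30 lay below the controls, 8 fell and 0 rose, with a median of -0.5784 (camera p = 1.23e-18, or 0.00108 with an estimated correlation). Under 19 alternatives, leaving out each array among them, the median lay between -0.77 and -0.48. The camera p, at the preset correlation in each, was at most 1.32e-15. The estimated correlation was not combined with these alternatives. The 8 included Usp18, an interferon-induced protease, at 2.09-fold lower, Dhx58, an RNA sensor, at 2.27-fold lower, and the transcription factor Irf7, at 1.84-fold lower. Of 7 probe sets shared by several class I histocompatibility genes, 3 fell, with log2 differences of -1.91 for H2-Q7 and H2-Q9, -1.32 for H2-Q6 and H2-Q8 and -1.41 for H2-Q4, H2-Q6 and H2-Q8 (adjusted p = 0.00280, 0.0141 and 0.0338). The others did not pass, that of H2-Q5 and H2-K1 at 0.32, H2-K1 and H2-D1 at -0.31, H2-T23 and H2-T-ps at -0.24 and H2-T9, H2-T10 and H2-T22 at -0.19 (adjusted p = 0.507, 0.425, 0.430 and 0.593). Macrophage and leukocyte markers had a median of -0.04 with 0 of 24 past the threshold. The pattern was found and tested on the same mice, and no technical explanation of it was tested. The strain background and housing of each genotype are not given in the sources used here, so a difference in either stays open.

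Besides the metallothioneins, Ddit4, an inhibitor of mTORC1 signalling, was 4.77-fold higher and Gadd45b 4.26-fold higher. A hypothesis was that glucocorticoid-induced genes are higher as a group. Of 13 others measured, 10 lay above the controls and 1 rose, Fkbp5, a glucocorticoid-inducible chaperone, at 2.31-fold. The median was 0.2983 (camera p = 0.00127, but p = 0.161 with an estimated correlation), and this list was not run under the other alternatives. The members did not move alike. Tsc22d3, Klf9, Dusp1 and Pck1 differed by 0.07, -0.02, -0.01 and -0.67 on the log2 scale. Cdkn1a and Lcn2 differed by 1.32 and 2.60 without passing, Lcn2 at 10534 ± 14373 in the knockouts. Several members are shared with lists fixed beforehand.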
